A study of Rattus norvegicus with 6 samples.

How the data were processed

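RNA of bone cells from newborn Sprague Dawley rats was measured on 6 arrays, 3 of cells attached to prothrombin (PT) and 3 of cells attached to osteopontin (OPN). Per the labels' protocols, the cells were adhered in coated multi-well plates, RNA was isolated with a column kit, and 300 ng was labelled with biotin by a whole-transcript assay without removal of ribosomal RNA. The arrays were Affymetrix Rat Gene 1.0 ST arrays, whose probes lie along the length of each transcript. Groups and replicate numbers were taken from the sample titles.

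The deposited table gives 1 intensity per probe set and array, on a linear scale. Per the submitters' processing notes it was made with Affymetrix Expression Console and PLIER, a method that summarises the probe intensities of a probe set. Versions, background correction, any scaling between arrays, filters and the genome build are not given in the sources used here. The scale was read from the deposited values, none of which lies below 0. The array medians differ slightly, so the arrays were not forced to 1 distribution. A scaling step changes how calls split between directions, which is why both alternative scalings stand beside the counts in the results. Detection calls were not used here, so dim rows carry an unknown share of background, which pulls their differences toward 0. Every column of the table was assigned to a sample, and replicates were not pooled.

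Rows were named through the annotation of the array platform, in which 15310 of 29215 rows had 1 gene symbol, 323 had several and 13582 had none. No gene was named from a row with several symbols, and rows without a name are unnamed here, not without a gene. The rows with 1 symbol comprised 14506 genes. Entrez identifiers of 15279 of these rows matched the GRCr8 gene table, which changed 0 symbols. Chromosome positions are not given because the build behind the array annotation is not named. For the 527 genes with more than 1 row, the row with the highest mean over the 6 arrays was used. Among named genes with several rows the differences of a gene's rows lay within 0.17 of each other (log2), Rhag has 2 identical rows, and Hspa8 has 8 rows, whose copies of the gene were not separated.

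Values were transformed as log2(intensity + 16), where 16 is an offset used with PLIER values, so that a fold difference is on this scale and understates the change of dim rows. A linear model with a term for the coating was fitted to each row with lmFit and eBayes of limma 3.58.1 in R 4.3.3. All 29215 rows entered the test, with no filter, and p-values were adjusted by the Benjamini-Hochberg method over all rows. Rows with an adjusted p below 0.05 are called, and rose and fell are used of called genes. Differences are OPN minus PT. A second count adds a log2 difference of at least 1. Replicate numbers 2 and 4 occur in both groups, but the labels do not say that they mark a shared preparation, so no block was used.

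Named genes follow a rule set before the data were examined, as did the lists, the tests and the alternative settings. They are 12 phenotype genes, the 12 genes per direction with the largest log2 difference among called rows whose arrays do not overlap between groups, and, per list, up to 4 members with the smallest p. Members of a called list whose value opposes it are named too. The 30 gene lists cover osteoclasts, the V-ATPase, macrophages, other cell types that bone and marrow hold, adhesion, proteases, signalling and metabolism. Of their 736 genes, 648 were named by the annotation used, so that Dcstamp, Nfatc1, Tnfrsf11a and Itgav, among others, were not analysed here. Lists of at least 5 measured genes were tested with camera on 1 row per gene, with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the lists. An estimated correlation and fry served as alternatives. With an estimated correlation camera also takes its p from the few residual degrees of freedom of the 6 arrays. A call lost there can reflect either change. Members were counted over all rows and adjusted over the list alone. List members held by another list number 8 of 22 in the osteoclast list, 7 of 27 in the macrophage list, 4 of 15 in the alternative activation list and 0 in the osteoblast, stromal and endothelial lists. Per array, the mean over the osteoclast list of log2 values centred per gene, minus that over the macrophage list, was compared by an exact two-sided permutation test.

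The test was checked on arrays simulated under its own assumptions, with each row's mean and normal noise at the row's eBayes-moderated spread. It recovered 70.1% of 67 rows moved by 0.5 on the log2 scale and 100% of those moved by 1 or 2, with 9 false calls among 29215 rows. In a second simulation over 14506 genes camera called the 1 list that was moved and 0 of 9 that were not. Genes were simulated independently of each other, so this does not check camera on lists of correlated genes.

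Alternatives changed 1 choice at a time, except that a variance trend and robust moderation were changed together. They were the replicate number as a block, quantile normalisation, equal array medians, leaving out the dimmest quartile or the dimmer part below the median of rows, only rows with 1 symbol, averaging the rows of a gene, a variance trend with robust moderation, array weights, no moderation, offsets of 1 and 64, each array left out in turn, and, for lists, genes held by only 1 list. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.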

Results

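Gene expression was measured in cells extracted from the long bones of Sprague Dawley rats aged 2 to 5 days and left to attach to plates coated with 1 of 2 proteins. Prothrombin (PT), from mouse, is the precursor of the clotting protease thrombin. Osteopontin (OPN), from bovine milk, is an acidic phosphoprotein of bone matrix that cells bind through integrins. RNA of the attached cells was read on Affymetrix Rat Gene 1.0 ST arrays, with 3 arrays of PT-adherent cells (replicates 1, 2 and 4) and 3 of OPN-adherent cells (replicates 2, 3 and 4). The table held 29215 rows, each the linear PLIER signal of 1 probe set, and the array medians lay between 207.8 and 231.4 units of signal. Correlations across rows were at least 0.988 between arrays of the same coating and at most 0.979 between coatings. No call of signal over background was used, so which rows lay above background is not known, and the number of arrays limits the precision. The labels do not say that the arrays came from separate animals or preparations, so the p-values measure only the spread between these samples, which may be technical.

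The design implies 1 comparison, OPN-adherent against PT-adherent cells, which asks how far the populations caught by the coatings differ in osteoclast and macrophage genes. Genes of bone matrix and matrix breakdown stood far higher in OPN-adherent cells. Ctsk, the collagen-degrading protease of osteoclasts, had a signal of 9057 ± 619 on OPN and 430 ± 46.8 on PT (SD, n = 3), a 20.4-fold difference. The mineral-binding matrix protein Ibsp was 14.7-fold higher, the collagenase Mmp13 14.02-fold and Spp1, which encodes osteopontin itself, 13.6-fold. Lower signals on OPN were more modest and led by macrophage genes. The haemoglobin scavenger receptor Cd163 had 753 ± 22.6 units on OPN and 1388 ± 105 on PT (SD, n = 3), a 1.82-fold difference in the other direction.

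In limma's test, 1700 of the 29215 rows passed an adjusted p of 0.05, 1475 of them higher and 225 lower on OPN. The rows carrying a single gene symbol comprised 1113 genes that rose and 163 that fell on OPN, while 399 of the called rows had no gene name in the annotation used. With at least a 2-fold difference, 288 rows were higher and 1 was lower. That 1 row, probe set 10701183, has no gene name here and was singled out after its values were seen (log2 difference -1.07, SE 0.23, adjusted p = 0.0282). It was dim, at 6.58 units on OPN and 30.1 on PT, and its call at this size was lost without OPN replicate 3 or without PT replicate 4, while 2 rows were called at this size in that direction without PT replicate 2 and 3 without OPN replicate 4. The 3 arrays of each coating did not overlap in any of the 1700 called rows, nor in 23.7% of all rows, against 10% by chance. The share of calls that were higher on OPN, 86.8%, fell to 68.1% with the array medians made equal and to 64.6% with quantile normalisation, which called 560 and 745 rows lower. Without OPN replicate 2 the test called 1080 rows, and without OPN replicate 3 it called 1023. The lower calls numbered 98 and 95 without those arrays, 99 without OPN replicate 4, 121 without PT replicate 2 and 129 without PT replicate 4.

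**Figure D1:**
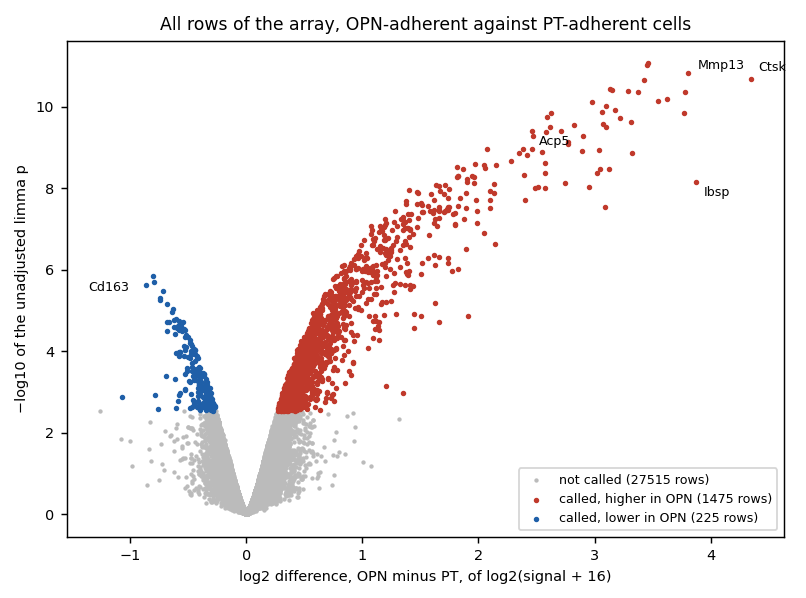
Each point is 1 row of the array, with the log2 difference (OPN minus PT, n = 3 arrays each) on the horizontal axis and −log10 of limma's unadjusted p on the vertical axis. The 1475 red points rose on OPN, by up to 4.35, and the 225 blue points fell, with -1.07 as the lowest called value.

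The 12 named genes that rose most on OPN had log2 differences between 3.32 and 4.35, each with an SE of at most 0.17. With Ctsk (4.35), Ibsp (3.87), Mmp13 (3.81) and Spp1 (3.77) stood the channel genes Panx3 (3.78) and Gja1 (3.63) and the protease inhibitors Serpine2 (3.55) and Tfpi2 (3.46). The membrane peptidase Mme (3.45), the collagen chaperone Serpinh1 (3.43), the matricellular protein Ccn1 (3.37) and the collagen cross-linking enzyme Lox (3.32) completed them. The 12 that fell most spanned -0.87 to -0.64. They held the scavenger and mannose receptors Cd163 (-0.87) and Mrc1 (-0.79), the complement components C1qa (-0.75) and C1qc (-0.68), and the lectins Clec4a3 (-0.67), Clec4a1 (-0.64) and Fcna (-0.64). The prostaglandin D synthase Hpgds (-0.81), the nuclease Dnase1l3 (-0.75), the sodium pump subunit Atp1b1 (-0.72), the receptor kinase Axl (-0.68) and the heme oxygenase Hmox1 (-0.68) made up the rest, and the adjusted p of these 12 was at most 0.00166.

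Osteoclast genes rose as a group on OPN. Acp5, which encodes the tartrate-resistant acid phosphatase that names these cells, was 5.50-fold higher, at 4782 ± 283 units on OPN and 856 ± 41.3 on PT (SD, n = 3), with adjusted p = 4.33e-07. Mmp9, a gelatinase of osteoclasts, was 7.48-fold higher and Itgb3, the integrin chain with which osteoclasts bind osteopontin, 3.34-fold (adjusted p = 5.07e-07 and 9.65e-06). The calcitonin receptor gene Calcr was dim, at 182 ± 24.2 units on OPN and 157 ± 10.5 on PT (SD, n = 3), and did not pass (adjusted p = 0.416). Of 22 measured osteoclast genes, 14 rose and 0 fell, with a median log2 difference of 0.53, and adjusted over the list alone 15 rose and 1, Acp2, fell. The proton pump subunit Atp6v0d2 was 5.35-fold higher. Acp2 (-0.26), a lysosomal phosphatase, and Car2 (-0.21), the carbonic anhydrase of the acid-secreting osteoclast, lay below 0 without a call. With equal array medians or quantile normalisation Acp2 was called lower, at adjusted p = 0.0387 and 0.0346. The list stood apart from the other genes in camera at adjusted p = 3.14e-14, but only with the preset correlation (adjusted p = 0.0678 with an estimated correlation). Of its 22 members, 8 also belong to another list. Markers of other cell types rose on the same arrays, with median log2 differences of 1.74 over the osteoblast list, 1.38 over the stromal list, 0.60 over the platelet list and 0.56 over the endothelial list.

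**Figure D2:**
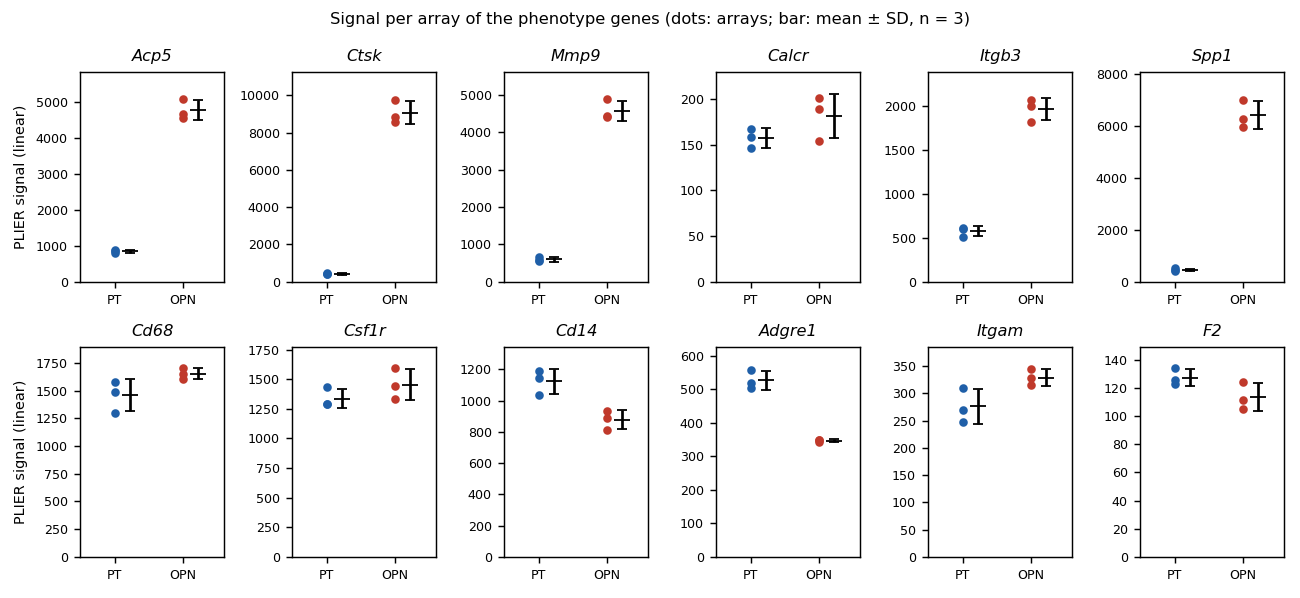
Linear PLIER signal of the 12 phenotype genes on each array, with PT in blue and OPN in red; dots are arrays and bars show the mean ± SD (n = 3). The axes start at 0, and the means of Acp5 go from 856 units on PT to 4782 on OPN while those of Calcr are 157 and 182.

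Subunits of the V-ATPase, the proton pump that acidifies lysosomes and the space beneath osteoclasts, rose by smaller amounts. Of 18 measured, 14 rose and 0 fell, with a median of 0.39, and adjusted over the list alone 14 rose and 1 fell. Besides Atp6v0d2, the named members were Tcirg1 (0.73), the pump's osteoclast-enriched membrane subunit, Atp6v1a (0.61) and Atp6v1g1 (0.57). Atp6v0a1 (-0.19) and Atp6v1b1 (-0.12), which encode alternative subunits, lay below 0, and Atp6v0a1 was called lower with quantile normalisation (adjusted p = 0.0396). The camera test gave adjusted p = 5.11e-09, and adjusted p = 0.209 with an estimated correlation. Without OPN replicate 2 or OPN replicate 3, 9 and 7 subunits were called higher, and 3 with the replicate number as a block. The lysosome list did not stand apart (adjusted p = 0.967, median 0.03). It held 7 genes that rose, led by Glb1 (0.90), Cd63 (0.72), Gusb (0.74) and Ctsl (0.56), and 2 that fell, Galc (-0.44) and Ctsc (-0.32), of 26 measured. Only 1 lysosomal gene was called lower when any 1 array was left out, and adjusted over the list alone 10 rose and 7 fell.

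In the list of RANK and M-CSF signalling, the pathways that drive osteoclast formation, the AP-1 genes Fos (1.74), Jun (1.01), Junb (0.80) and Fosl2 (0.57) and the repressor gene Prdm1 (0.28) rose, and the transcription factor gene Tfec (-0.32) fell. The other 26 of 32 measured genes were not called, and the list had an adjusted p of 0.103 (median 0.12). Fos, Jun and Junb also belong to the list of immediate early and dissociation stress genes, which rose on the same arrays (14 of 22, median 0.66), and with genes of only 1 list RANK and M-CSF signalling had an adjusted p of 0.902. Adjusted over the list alone 9 rose and 3 fell. In that list 0 genes were called lower without PT replicate 2, PT replicate 4 or any 1 of the 3 OPN replicates, and 2 without PT replicate 1, with equal array medians or with quantile normalisation. Of 17 measured genes of cell fusion, the immunoglobulin-type membrane gene Cd200 (1.57) and the membrane-spanning protein genes Cd9 (1.20), Tm4sf19 (0.72) and Cd81 (0.55) rose, and Cdh1 (-0.54), the E-cadherin gene, fell. This list had an adjusted p of 0.972 and a median of 0.06, with 5 rising and 4 falling adjusted over the list alone, and 3 were called lower over all rows with either scaling of the arrays. Galc, Ctsc, Prdm1, Tfec, Cd81 and the lower cytokine genes given below were named after their values were seen, because their groups held 5 genes or fewer.

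Macrophage genes fell as a group on OPN, though not all of them. Of 27 measured, 14 fell and 0 rose, with a median of -0.35 (adjusted p = 3.29e-13 in camera, adjusted p = 0.0678 with an estimated correlation), and adjusted over the list alone 16 fell and 1 rose. Beside Cd163, Mrc1 and C1qa, the cytoskeletal gene Aif1 (-0.61) fell. Adgre1, an adhesion receptor gene that marks rat macrophages, had 347 ± 3.40 units on OPN and 527 ± 28.6 on PT (SD, n = 3), a 1.495-fold difference with adjusted p = 0.00134. The endotoxin co-receptor Cd14 was 1.27-fold lower (adjusted p = 0.0479), a call that was lost without each array except PT replicate 1, with adjusted p between 0.0861 and 0.189. The M-CSF receptor gene Csf1r (0.12, SE 0.09) and the lysosomal glycoprotein gene Cd68 (0.18, SE 0.09) did not pass, with signals on PT of 1337 ± 84.2 and 1455 ± 145 units (SD, n = 3). The integrin gene Itgam (0.24, SE 0.09), Lyz2 (0.26, SE 0.16), Vsig4 (0.14), Fcgr2b (0.11) and Ccr2 (0.08) also lay above 0 without a call, and Vsig4 turned to -0.01 without PT replicate 2. On the same arrays the erythroid list had a median of -0.24 and the cell cycle list -0.18. The osteoclast list had 0.53 and the granulocyte list 0.17. Whether osteoclasts or granulocytes carried RNA of the macrophage genes above 0 was not measured. Those genes therefore cannot be read as unchanged in macrophages.

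Set against each other per array, the osteoclast and macrophage lists separated the coatings. The mean centred log2 value of the osteoclast genes minus that of the macrophage genes was 0.67 ± 0.025 on OPN and -0.67 ± 0.024 on PT (SD, n = 3 each), a difference of 1.34. The exact two-sided permutation test gave p = 0.1, the smallest p that 3 against 3 arrays allow. The lists share 0 measured genes.

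Genes of antigen presentation and of alternative macrophage activation moved little. In the list of MHC class II antigen presentation, 2 of 17 measured genes fell, the costimulatory gene Cd86 (-0.63) and the protease gene Ctss (-0.39), whose call was lost without OPN replicate 2 (adjusted p = 0.0612). RT1-Da (-0.21) and RT1-Ba (-0.20), which encode class II chains, did not pass, and Cd40 (0.14), RT1-DOb (0.08), RT1-DOa (0.03) and Ciita (0.03) lay above 0. RT1-DOa and Ciita both turned below 0 with either scaling of the arrays (each to -0.04 with equal medians) and without OPN replicate 2, RT1-DOa also without OPN replicate 4 and Ciita without PT replicate 4. The list had a median of -0.05 and an adjusted p of 0.00312 (adjusted p = 0.116 with an estimated correlation), and 2 genes fell adjusted over the list alone. The alternative activation list was called lower at adjusted p = 0.0224 (adjusted p = 0.219 with an estimated correlation) with a median of -0.03. Its 2 genes that fell, Cd163 and Mrc1, are scavenging receptors that also stand in the macrophage list, and the call was lost with genes of only 1 list (adjusted p = 0.726) and with quantile normalisation (adjusted p = 0.0726). Clec10a (-0.24) was called with quantile normalisation alone among the scalings (adjusted p = 0.0489). Il4r (0.25), Arg1 (0.22), Clec7a (0.09), Ccl24 (0.10), Retnla (0.09), Cd209a (0.10) and Ccl17 (0.06) lay above 0, and adjusted over the list alone 1 gene rose and 2 fell. Retnla fell to -0.03 without PT replicate 2, and Cd209a to -0.07 and Ccl17 to -0.02 without OPN replicate 2.

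Osteoblast and stromal genes gave the largest medians of the 30 lists on OPN, 1.74 and 1.38 (log2). Of 21 measured osteoblast genes, 19 rose and 0 fell, also adjusted over the list alone. The matrix glycoprotein Sparc had 1128 ± 37.4 units on PT and was 8.76-fold higher on OPN, and the endopeptidase gene Phex of osteocytes was 8.86-fold and the collagen gene Col1a2 5.54-fold higher. Sost (-0.01, SE 0.10), the gene of the osteocyte protein sclerostin, did not differ beyond its error and turned to 0.05 and 0.07 without PT replicate 4 and OPN replicate 3. Camera called the osteoblast list at adjusted p = 2.31e-28 (adjusted p = 0.0678 with an estimated correlation). Of 17 measured stromal fibroblast genes 16 rose and 1 fell, also adjusted over the list alone (adjusted p = 4.57e-25 in camera, adjusted p = 0.0654 with an estimated correlation). The proteoglycan genes Lum (3.31) and Bgn (3.18) rose with Igfbp5 (2.59), which encodes a binding protein of insulin-like growth factors, and Fstl1 (2.38). The gene that fell, Vcam1 (-0.53, adjusted p = 0.00165), encodes an adhesion molecule of stromal and endothelial cells that is also made by macrophages.

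Matrix proteases and their inhibitors rose together, 12 of 22 measured and 0 in the other direction, also adjusted over the list alone. Mmp13 was joined by the protease inhibitor Timp1 (3.07), Mmp9 (2.90) and the protease Adamts1 (2.62), while Mmp7 (-0.09) and Adam17 (-0.02) lay below 0. The list had a median of 0.53 and adjusted p = 1.51e-13 (adjusted p = 0.0654 with an estimated correlation). Cell type markers moved as well, with medians of 1.74 over the osteoblast list, 1.38 over the stromal list, 0.53 over the osteoclast list and -0.35 over the macrophage list. The chondrocyte list was not called (adjusted p = 0.103, median 0.10), with 14 of 18 measured genes uncalled. Its fibrillar collagen genes Col11a1 (3.29), Col11a2 (1.42) and Col2a1 (0.41) rose and the transcription factor gene Sox6 (-0.36) fell, and adjusted over the list alone 4 rose and 1 fell. Without PT replicate 1 the list passed (adjusted p = 0.0373). The call of Col2a1 was lost without PT replicate 2 or 4 or OPN replicate 2 or 3 (adjusted p between 0.0506 and 0.0726) and that of Sox6 without OPN replicate 2 (adjusted p = 0.0700).

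Endothelial genes rose on OPN, 9 of 17 measured and 13 adjusted over the list alone, with a median of 0.56. The receptor genes Kdr (1.15), Tek (1.09) and Ramp2 (0.81) and the diaphragm gene Plvap (0.61) led them, and 0 fell (adjusted p = 4.24e-10, adjusted p = 0.116 with an estimated correlation). In the megakaryocyte and platelet list 8 of 11 measured genes rose and 0 fell, with a median of 0.60 (adjusted p = 4.24e-05, adjusted p = 0.116 with an estimated correlation). The matrix protein Thbs1 (1.32), the adhesion receptors Selp (1.14) and Gp1ba (0.71) and the platelet chemokine Pf4 (0.80) were highest in significance. The transcription factor genes Gfi1b (-0.28) and Nfe2 (-0.10) and the receptor gene P2ry12 (-0.15) lay below 0, and adjusted over the list alone Gfi1b fell. Over all rows Gfi1b was called lower with equal array medians (adjusted p = 0.0355), with quantile normalisation (adjusted p = 0.0274) and without PT replicate 1 (adjusted p = 0.0486).

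Because 1 coating is a clotting factor, genes of coagulation and fibrinolysis were listed too. Of 27 measured, 14 rose and 0 fell, with a median of 0.36, and 18 rose and 1 fell adjusted over the list alone. Cell type markers rose on the same arrays, with medians of 1.38 over the stromal list, 0.56 over the endothelial list and 0.60 over the platelet list. Tfpi2 and Serpine2, inhibitors of serine proteases, were followed by Vkorc1 (1.97), the vitamin K reductase, and Pros1 (1.35), the anticoagulant protein S gene. F2, which encodes prothrombin, was dim and did not pass, at 114 ± 9.85 units on OPN and 127 ± 5.97 on PT (SD, n = 3; log2 difference -0.15, adjusted p = 0.397). The receptor gene F2rl1 (-0.23), Serpinc1 (-0.17), F10 (-0.07), F7 (-0.06), Proc (-0.04) and Plau (-0.02) also lay below 0. F2rl1 was called lower with equal array medians (adjusted p = 0.0406) and with quantile normalisation (adjusted p = 0.0316), Plau turned to 0.05 without PT replicate 2 and 0.03 without OPN replicate 4, and Proc to 0.04 without PT replicate 1. The list had adjusted p = 2.05e-08 (adjusted p = 0.116 with an estimated correlation), and 9 members were called higher without OPN replicate 2.

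Among integrins and their adaptors, the receptors through which cells hold to such coatings, 8 of 26 measured genes rose and 1 fell, with a median of 0.19. On the same arrays the medians of cell type markers were 1.74 over the osteoblast list, 1.38 over the stromal list, 0.60 over the platelet list, 0.56 over the endothelial list and -0.35 over the macrophage list. Itgb3 (1.74) was followed by Itgb1 (0.72), Itga1 (0.69) and the actin linker gene Vcl (0.62). The leukocyte integrin gene Itgal (-0.40) fell, a call lost without PT replicate 2 or 4 and without OPN replicate 2 or 4 (adjusted p between 0.0632 and 0.105). Itga4 (-0.25), Itgad (-0.22), Itgb2 (-0.14), Itga7 (-0.04) and Itgb5 (-0.01) lay below 0, and the last pair turned to 0.02 without OPN replicate 4. The list was called at adjusted p = 0.00480 (adjusted p = 0.219 with an estimated correlation), but not with the dimmer rows below the overall median left out (adjusted p = 0.0685). Adjusted over the list alone 13 rose and 2 fell, and without OPN replicate 2 or without OPN replicate 3 the test over all rows called 5 higher.

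Immediate early and dissociation stress genes, which cells switch on within minutes of handling, also stood higher on OPN. Of 22 measured, 14 rose and 0 fell, with a median of 0.66 (adjusted p = 1.27e-10, adjusted p = 0.116 with an estimated correlation), and 16 rose and 1 fell adjusted over the list alone. Ccn1, Fos (1.74), the stress factor gene Atf3 (1.70) and the mRNA-destabilising gene Zfp36 (1.19) led them. Egr3 (-0.21), Nr4a1 (-0.07) and the heat shock genes Hspa8 (-0.10) and Hsph1 (-0.01) lay below 0 without a call. Hspa8 has 8 rows under its symbol, with values between -0.10 and 0.04, which leaves its sign uncertain, and Hsph1 turned to 0.01 without PT replicate 1. Marker medians on these arrays were 1.74 over the osteoblast list, 1.38 over the stromal list, 0.56 over the endothelial list and -0.35 over the macrophage list. The cytokine list went both ways, with 7 of 35 measured genes rising and 5 falling, and was not called (adjusted p = 0.217, median 0.01). The neutrophil chemokine Cxcl1 (1.33), the macrophage growth factor Csf1 (1.05), Ccl9 (0.81) and the prostaglandin synthase Ptgs2 (0.84) rose. The inflammatory genes Ccl3 (-0.62), Il1a (-0.59), Il1b (-0.42), Ccl4 (-0.32) and Ccl7 (-0.32) fell, and 2 genes were called lower without each array other than PT replicate 1. Adjusted over the list alone 7 rose and 8 fell.

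Genes of glucose uptake and glycolysis rose in part, 6 of 21 measured, with a median of 0.27 (adjusted p = 0.00567, adjusted p = 0.473 with an estimated correlation). The glucose transporter genes Slc2a3 (0.69) and Slc2a1 (0.35) and the enzyme genes Hk2 (0.48) and Pfkp (0.44) were the named risers. Hk1 (-0.20), Pfkm (-0.15) and Pfkfb4 (-0.06) lay below 0, Hk1 with a call once array medians were equal (adjusted p = 0.0466), and adjusted over the list alone 11 rose and 1 fell. Without OPN replicate 2, OPN replicate 3 or PT replicate 2, 2, 2 and 3 genes were called higher. With the replicate number as a block 0 were, and the list lost its call (adjusted p = 0.0622 in camera). The call of Slc2a1 was lost without OPN replicate 2 (adjusted p = 0.0687) or 3 (adjusted p = 0.0638), and that of Pfkp without each array except PT replicate 1 (adjusted p between 0.0654 and 0.141). In the oxidative phosphorylation list 1 of 56 measured genes rose, Ndufb5 (0.40), a call lost with equal array medians (adjusted p = 0.0892) and without each array except PT replicate 4 (adjusted p between 0.0741 and 0.148). Sdhc (0.25), Uqcrq (0.25) and Cox5a (0.21) did not pass, 0 were called adjusted over the list alone, and the list itself had an adjusted p of 0.103 and a median of 0.10. That list passed with quantile normalisation (adjusted p = 0.0479), without PT replicate 4 (adjusted p = 0.00868) and without OPN replicate 2 (adjusted p = 0.0390).

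Erythroid and cell cycle genes stood slightly lower on OPN. All 14 measured erythroid genes lay below 0, with a median of -0.24 (adjusted p = 6.58e-09, adjusted p = 0.219 with an estimated correlation), and 10 fell adjusted over the list alone. Over all rows 4 fell, Rhd (-0.35), Epb42 (-0.35), Sptb (-0.34) and Rhag (-0.30), which encode red cell membrane proteins, with adjusted p between 0.0205 and 0.0486. These calls were fragile, as 1 remained without OPN replicate 3 and 0 without OPN replicate 2, OPN replicate 4, PT replicate 2 or PT replicate 4. The signals were high on both coatings, with Rhag at 4992 ± 291 units on PT (SD, n = 3). All 23 measured cell cycle genes lay between -0.28 and -0.04 (adjusted p = 2.13e-10, adjusted p = 0.293 with an estimated correlation). In the test over all rows 0 of them passed, against 8 adjusted over the list alone, 3 with equal array medians and 8 with quantile normalisation. The replication genes Mcm6 (-0.24), Mcm7 (-0.23) and Rrm2 (-0.26) and the mitotic kinase gene Aurka (-0.28) had unadjusted p between 0.00521 and 0.00865.

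The remaining lists were not called. Of 19 measured granulocyte genes 0 passed, over all rows or adjusted over the list alone, and the list had a median of 0.17 and an adjusted p of 0.0923. Its granule genes Lcn2 (0.57, SE 0.21), Mmp8 (0.43), Camp (0.32) and Fcnb (0.26) varied between arrays. Without PT replicate 4 the list was called (adjusted p = 2.49e-05) with 7 members higher, among them Lcn2, Mmp8 and Camp. The list also passed without OPN replicate 2 (adjusted p = 0.0150) and with quantile normalisation (adjusted p = 0.0373). Mast cell and basophil genes (adjusted p = 0.259, median 0.13), with Il1rl1 (0.27), Mcpt8 (0.48), Hdc (0.22) and Mrgprx2 (0.17), had 0 calls of 14 measured, over all rows or adjusted over the list alone. Mcpt8 was called higher without PT replicate 4 (adjusted p = 0.00746). The B lymphoid list (adjusted p = 0.778, median 0.03) had 0 calls of 12, with Ebf1 (0.33), Igll1 (0.15), Blnk (0.14) and Cd22 (-0.20), and Ebf1 rose adjusted over the list alone and without PT replicate 4 (adjusted p = 0.0318). In the T and NK lymphoid list (adjusted p = 0.417, median 0.07) Cd4 (-0.41), a gene that rat macrophages also express, fell alone of 19 measured, also adjusted over the list alone. Il7r (-0.36), Lck (0.23) and Prf1 (0.18) did not pass.

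Adipocyte genes (adjusted p = 0.121, median -0.06) had 1 rise among 10 measured, the lipase gene Lpl (0.46), a call lost without OPN replicate 3 (adjusted p = 0.0546). Fabp4 (-0.28) was called lower adjusted over the list alone and with quantile normalisation (adjusted p = 0.0490), and Cfd (-0.15) and Pparg (-0.15) did not pass. Skeletal muscle genes (adjusted p = 0.184, median -0.02) had 0 calls among 15, over all rows or adjusted over the list alone, with Des (0.34), Myh4 (0.16), Acta1 (-0.21) and Pvalb (-0.14). Without PT replicate 4 the adipocyte and muscle lists passed, at adjusted p = 0.0189 and 0.0498. Of 26 measured interferon response genes (adjusted p = 0.411, median -0.0019) the chemokine gene Cxcl10 (0.60) rose, also adjusted over the list alone, and Bst2 (0.22), Irf9 (0.17) and Mx1 (-0.16) did not pass. The 48 measured cytosolic ribosomal protein genes gave 0 calls in either adjustment (adjusted p = 0.264, median 0.02), with values between -0.15 for Rps3 and 0.22 for Rps15, and Rpl15 (0.12) and Rps24 (0.10) between them. Without PT replicate 1 that list passed (adjusted p = 0.00156). The means of the B lymphoid, T and NK lymphoid, cytokine, interferon, cell fusion and ribosomal lists lay above 0 while camera, which compares a list with all other genes, placed them below.

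Over the 30 lists, 16 were called with the preset correlation of 0.01, 0 with an estimated correlation, where the lowest adjusted p was 0.0654, and 19 by fry, which tests whether a list moves one way without reference to other genes.

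**Figure D3:**
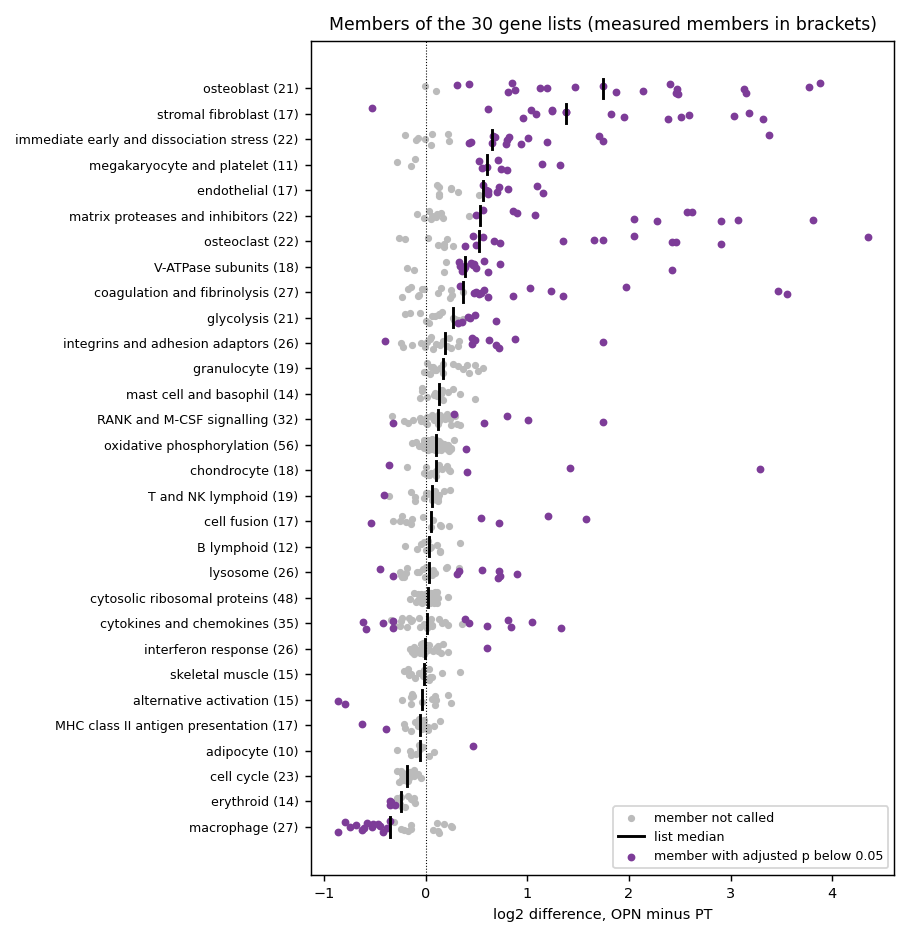
Log2 difference, OPN minus PT, of each measured member of the 30 gene lists (dots; purple where limma's adjusted p was below 0.05), with a bar at each list's median and the number of measured members in brackets. Medians run from 1.74 for the osteoblast list to -0.35 for the macrophage list, where 14 of 27 members fell.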

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

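All tests in this part were planned. Of 181 named genes, 94 were called, and 0 of these changed sign in any of the 18 alternatives that refit the rows, each changing 1 choice but for a variance trend and robust moderation, which were changed together. In all 18 where they were measured 71 kept their call, and 23 lost it in at least 1. Of the 1700 called rows, 1533 were still called with quantile normalisation, 1421 with equal array medians, 1512 with offset 1, 1677 with offset 64 and between 1011 and 1323 with 1 array left out. None of the 1700 took the opposite sign in these settings. The scalings moved the median of all rows from 0.03 to -0.03 and -0.04 (log2), so which weak genes count as lower depends on them. Signal over background was not assessed here, and dim rows can show differences only in part.

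The replicate number as a block gave 666 calls, 618 higher and 48 lower, with 615 shared with the 1700, and no moderation gave 1102, 914 of them higher, with 945 shared. A block spends degrees of freedom. Replicate numbers 1 and 3 each occur on only 1 coating, so with the block the difference rests on the arrays numbered 2 and 4. Without moderation each row relies on its own spread. The numbers 2 and 4, which both coatings have, gave correlations of -0.08 and 0.07 between deviations from the group means. These values show no sign of pairing, but so few shared numbers cannot exclude it. With the block, members called higher numbered 3 of the V-ATPase list (14 as reported), 0 of glycolysis (6), 3 of integrins (8), 5 of platelet genes (8), 8 of coagulation (14), 4 of cytokines (7), 3 of the lysosome (7), 3 of RANK signalling (5) and 0 of the adipocyte, interferon and oxidative phosphorylation lists (1 each). Members called lower numbered 8 of the macrophage list (14), 0 of erythroid genes (4), 1 of MHC class II (2), 1 of cytokines (5), 0 of the lysosome (2) and 0 of the chondrocyte, stromal, T and NK, integrin and RANK lists (1 each). The 225 lower calls became 745 with quantile normalisation, 560 with equal array medians, 418 with the dimmest quartile left out, 553 with the dimmer part below the median left out, 361 with only rows of 1 symbol, 516 with a variance trend and robust moderation, and 382 with offset 64. Equal medians lower all log2 differences by the same amount, and the filters test fewer rows, while for quantile normalisation, the trend with robust moderation and the offset the cause was not tested. The 1 lower call of at least 2-fold became 3 with the block, 2 with equal medians, 2 with offset 1 and 0 with either filter on dim rows, only rows of 1 symbol, array weights, no moderation or offset 64. With 1 array left out the calls numbered 1023 to 1486, those higher 928 to 1357, those lower 95 to 181 and those lower by at least 2-fold 0 to 3, from tests with fewer samples.

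Genes that changed sign were not called. Quantile normalisation and equal medians turned Ciita to -0.032 and -0.040, RT1-DOa to -0.038 and -0.040, and Ccl17 to -0.020 and -0.0072. The block turned Sost to 0.047, Itga7 to 0.00042, Proc to 0.058, Mmp7 to 0.041 and Hsph1 to 0.015. With 1 array left out the values spanned -0.018 to 0.073 for Ciita, -0.035 to 0.12 for RT1-DOa, -0.017 to 0.13 for Ccl17, -0.011 to 0.23 for Vsig4, -0.029 to 0.16 for Retnla and -0.070 to 0.19 for Cd209a. They spanned -0.091 to 0.072 for Sost, -0.11 to 0.018 for Itga7, -0.046 to 0.024 for Itgb5, -0.11 to 0.041 for Proc, -0.057 to 0.045 for Plau and -0.032 to 0.013 for Hsph1. All lie near 0, and the cause was not tested.

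All 16 lists called by camera lost their call with an estimated correlation between genes. There camera also takes its p from the few residual degrees of freedom of the arrays. These changes were not tested apart. The estimate was above the preset 0.01 for all of them but MHC class II (0.0054). A higher correlation therefore cannot be why the MHC class II list lost its call. The adjusted p was then 0.0678 for the osteoclast, macrophage and osteoblast lists, 0.0654 for the stromal and protease lists, 0.116 for MHC class II, endothelial, platelet, coagulation and immediate early genes, 0.209 for the V-ATPase, 0.219 for alternative activation, erythroid genes and integrins, 0.293 for the cell cycle and 0.473 for glycolysis. In the other alternatives 13 of the 16 kept adjusted p at or below 0.0387. The exceptions were alternative activation (0.0726 with quantile normalisation, 0.726 with genes of only 1 list), integrins (0.0685 with the dimmer rows below the median left out) and glycolysis (0.0622 with the block).

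The 14 lists without a call changed more. Granulocyte genes passed with quantile normalisation (0.0373) and with the trend and robust moderation (0.0359), chondrocyte genes with the block (0.0287) and with fry (0.00305), RANK signalling with fry (0.0214), oxidative phosphorylation with quantile normalisation (0.0479) and ribosomal proteins with the block (0.000166). Fry, which asks whether a list differs from 0 and not from the other genes, gave the other direction for B lymphoid (0.665), T and NK (0.789), cytokine (0.2505), interferon (0.665), cell fusion (0.0450) and ribosomal genes (0.816). The direction also changed for interferon genes with the dimmer rows left out (0.682), for the lysosome with the block (0.528) and array weights (0.896), for oxidative phosphorylation with the block (0.835) and for ribosomal proteins with quantile normalisation (0.469). Cell fusion genes changed direction with quantile normalisation (0.726), equal medians (0.750), the trend and robust moderation (0.846), offset 64 (0.922) and genes of only 1 list (0.776). Apart from fry, the cause was not tested. With 1 array left out the adjusted p spanned 2.49e-05 to 0.635 for granulocyte, 0.0373 to 0.289 for chondrocyte, 0.465 to 0.866 for B lymphoid, 0.0498 to 0.452 for muscle, 0.0189 to 0.325 for adipocyte, 0.481 to 0.959 for lysosome, 0.635 to 0.890 for cell fusion, 0.00868 to 0.762 for oxidative phosphorylation and 0.00156 to 0.868 for ribosomal genes. Over all alternatives the range was 0.0214 to 0.902 for RANK signalling, 0.191 to 0.714 for cytokines and 0.218 to 0.803 for interferon genes.

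The score of the osteoclast list minus that of the macrophage list, 1.34 as reported, came to 1.52 with the dimmer rows below the median left out, which removes dim members, to 1.37 with offset 1 and to 1.24 with offset 64, which shrinks dim genes more, and to between 1.32 and 1.35 with 1 array left out. Lists were not run without moderation, since camera moderates on its own. That score has no test per row, so moderation, robust or not, and trend do not apply to it, nor does the restriction to rows of 1 symbol.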

Other observations

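The lists of collagen processing, heme and iron handling and apoptotic cell clearance were chosen after the genes that named them were seen, as were the tests of dilution, of macrophage array scaling, of other cell types rising alike and of marrow cell types falling alike. The genes that prompted each list were left out of it. A hypothesis drawn from Serpinh1, Plod2 and Fkbp10 is that the machinery that folds and modifies collagen stood higher on OPN, beside the collagen genes. Of 14 other genes of that machinery, 12 rose and 0 fell (median 1.12, adjusted p = 1.25e-17 over the 3 added lists, adjusted p = 0.0470 with an estimated correlation). Crtap (2.15) and P3h1 (1.51), which act together in proline hydroxylation of collagen, the procollagen protease Bmp1 (2.13) and the transcription factor gene Creb3l1 (1.59) were among them. Plod1 (-0.02), a lysyl hydroxylase, did not pass. More collagen-making cells on OPN may account for this, and the arrays do not separate that from higher expression per cell.

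A hypothesis drawn from Hmox1, Slc40a1 and Cd163 is that heme and iron handling by macrophages stood lower on OPN. In 14 other genes the list lay lower than the remaining genes (adjusted p = 0.000391, adjusted p = 0.0597 with an estimated correlation), with a median of -0.22. Its mean was only -0.08 (SE 0.11 over genes), because Cp (1.27), the ferroxidase ceruloplasmin, rose, and over all rows only the heme transporter Slc48a1 (-0.47) fell. The ferritin chains Fth1 (-0.23) and Ftl1 (-0.22) did not pass. On the same arrays the macrophage list had a median of -0.35 and the erythroid list -0.24. The arrays do not separate lower expression per macrophage from a change in the cell mixture. A hypothesis drawn from Axl and Nr1h3, lower clearance of apoptotic cells on OPN, did not pass in 10 other genes (adjusted p = 0.570, adjusted p = 0.585 with an estimated correlation, median 0.06). Mertk (-0.44) and Abcg1 (-0.40) fell while Mfge8 (0.81), Anxa1 (0.68) and Elmo1 (0.59) rose.

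Macrophage genes stood lower on OPN, and dilution by RNA of other cells is a possible explanation. If the other cells carried none of these RNAs, dilution alone would lower macrophage genes as far as erythroid and cell cycle genes. Whether those cells carried cell cycle RNA or RNA of the macrophage list was not measured, so neither comparison can decide. Of the 27 macrophage genes 7 lay above 0 without a call, which draws that list's mean toward 0. The macrophage mean lay below the cell cycle mean (-0.12, SE 0.028) but barely below the erythroid mean (-0.072, SE 0.035, 2.05 standard errors). With each array left out the cell cycle difference stayed between 2.68 and 6.33 standard errors, while the erythroid difference came to 1.43, 1.79 and 1.87 without PT replicate 4, OPN replicate 3 and OPN replicate 4, to 2.22 and 2.34 without PT replicate 2 and OPN replicate 2, and to 2.20 without PT replicate 1, where it shrank to -0.040. Dilution alone therefore stays open, although 14 of 27 macrophage genes lay below -0.35, the lowest of the 37 erythroid and cell cycle genes. A difference in array medians does not account for the fall, since equal array medians took the list's median from -0.35 to -0.41. That step lowers all differences by the same amount, so it cannot test other forms of scaling. An effect of the coating on which macrophages attach or on their expression stays open and untested.

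Osteoblast and stromal genes rose with osteoclast genes on OPN. A lower share of macrophages alone could raise every other cell type alike, granulocytes included, but the osteoblast mean rose 1.52 further than the granulocyte mean (SE 0.13), and the stromal mean 1.495 further (SE 0.13), which argues against that. A lower share of all marrow cell types would lower their genes alike. The granulocyte mean moved 0.45 above the erythroid mean (SE 0.10) and 0.52 above the macrophage mean (SE 0.12), by at least 2.58 standard errors with any 1 array left out. That argues against such a lower share only weakly, since the granulocyte list was not called (adjusted p = 0.0923 in camera) and varied between arrays. A lower share of only some marrow types stays open. Whether osteoclasts and bone-forming cells each attach more to OPN or arrive together as attached pieces of bone surface was not tested. The share of each cell type was not measured, so the rise of osteoclast genes cannot be read as expression per cell.

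Calls of at least 2-fold were almost all higher on OPN, 288 against 1. The calls stayed one-sided, with 267 higher and 2 lower with equal array medians and 265 and 1 with quantile normalisation. These steps moved the median of all rows only from 0.03 to -0.04 and -0.03 (log2), too little to even out calls of this size. They cannot test a scaling made before the values were deposited, so scaling as a cause stays undecided. The offset added before the log is argued against as the cause, with 314 higher and 2 lower at an offset of 1. An effect of the coating on the cells that attach stays open and was not tested apart from the cell mixture.

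Of the 10 splits of the 6 arrays into 3 and 3, 1 split, the real one, gave as many called rows (1700, against 0 as the highest of the others). For calls of at least 2-fold it was also 1 of 10 (289, against 0 as the highest of the others). The splits are too few for a share under 0.05.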
